A study of Sisymbrium orientale with 12 samples.

How the data were processed

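RNA was taken from the youngest expanded leaf of untreated plants of 12 lines, and strand-specific poly(A) libraries were made with a TruSeq kit, per the labels. The authors deposited a table of normalized values per contig and library, an annotation table that gives each contig an Arabidopsis locus, and a table of their own comparison. Per the submitters' processing notes, Bowtie2, SAMtools 1.3.1, edgeR, R 3.3 and the Arabidopsis annotation TAIR10 were used; the role and order of each, and how reads matching contigs of both assemblies were counted, are not given in the sources used here. Contig names in the deposited table show 2 Trinity assemblies, marked R and S. The deposited values are a normalized signal (read coverage per contig as CPM on a scaled library size): each column sums to between 915639 and 1180040, so they are not plain CPM, and dividing each column by its smallest step gave whole numbers for 100% of values within 0.1. The largest deviation from a whole number was 6.956e-04. The whole reads recovered in this way number 100976000 to 145937000 per library. The authors' deposited comparison holds log2 fold changes and p-values with their FDR; every listed contig has a p-value of at most 0.0498 and an absolute log2 fold change of at least 1.00.

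The design written in advance assumed CPM, and its test for CPM was kept because the values are CPM up to the scaling factor. Values were tested with limma 3.58.1 (R 4.3.3) as log2(CPM + 0.5) with a mean-variance trend and Benjamini-Hochberg adjustment, and contigs were kept with at least 1 CPM in at least 5 libraries (31337 of 33277, 94.2%). Fold changes on this scale understate the change of low contigs. The comparison of phenotypes used all 12 libraries with cross as a covariate, comparisons within a cross and the difference between crosses used a model with 1 mean per group, and the comparison of crosses had the phenotype as a covariate. IAA2 was tested with an exact two-sided permutation of the phenotypes within each cross (300 arrangements). Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists with at least 5 contigs; list members were found through the Arabidopsis locus or the annotation's wording. The window around IAA2 took about 100 loci on each side in Arabidopsis order, which need not be the order in Sisymbrium. No genome of the species was used here, so no position in it can be given.

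On the recovered reads, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 were run as alternatives. DESeq2 has no counterpart of camera and was not run for the lists. Other alternatives were pseudocounts of 0.1 and 2, no filter or 1 CPM in 2 libraries, rescaling by the median ratio, robust=TRUE in limma, no covariate, windows of about 50 and 200 loci, and each library left out in turn. CPM summed per locus, the edgeR exact test, the unadjusted criterion for the window, and the sums by assembly and ratio of R-assembly to S-assembly contigs were added after seeing the data. Contigs of 1 locus can share reads, so each is uncertain by itself and neighbouring contigs are not independent.

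Contigs named in the text were chosen by a rule written in advance. Per comparison with calls it took up to 12 contigs in each direction with the largest difference among those called that had the same sign in both crosses (for the crosses, in both phenotypes), 1 per locus. With fewer than 5 of these, it took the 5 with the smallest p, as values only. To these it added all contigs of IAA2, up to 4 contigs per list by smallest p, and called contigs near IAA2. The remaining contigs called within cross B, all those named as other contigs of a locus, AT3G22680, IAA7 and P-glycoprotein 13 were named after their values were seen.

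The steps were tested on simulated data with 100 contigs changed by 2-fold and 100 by 4-fold. For phenotypes over all libraries limma recovered 71% and 91% of them among 30589 contigs, with 7 false calls. Within cross A it recovered 21% and 90% (30577 contigs), within cross B 19% and 86% (30576), for the difference between crosses 2% and 70% (30580) and for the crosses 74% and 92% (30568). A planted list of 30 contigs had a camera adjusted p of 2.596e-43, with 0 of 25 other lists called. Contigs were simulated independently of each other, so this does not test lists whose genes vary together, as they can in the real libraries. Apart from the planted changes, each contig also had the same expected share of reads in all libraries. False calls from shifts shared by many contigs were therefore not tested either. The changed contigs were drawn above a minimum level, so the recovered shares do not cover the lowest contigs. Figures were drawn with matplotlib.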

Results

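Leaf RNA was sequenced from lines of Sisymbrium orientale (Indian hedge mustard), a weedy relative of Arabidopsis, that were either resistant or susceptible to 2,4-D, a herbicide that acts as a synthetic auxin. The youngest expanded leaf of untreated plants was taken at the stage given in the labels, so the libraries show leaves that had not met the herbicide. The 12 libraries came from 2 crosses, with cross A at generation 4 and cross B at generation 3, so cross and generation cannot be told apart. Cross A held 3 resistant lines (R202, R206 and R221) and 3 susceptible lines (S205, S207 and S242), and cross B held 2 resistant lines (RP6 and RP8) and 4 susceptible lines (SP3, SP7, SP9 and SRP1), numbered in that order within each group. The table gave 33277 assembled transcripts, called contigs here, of which 12416 came from an assembly marked R and 20861 from an assembly marked S. Each contig was annotated with its closest Arabidopsis locus, and 4287 of the 16386 loci had contigs of both assemblies. The values came from 100976000 reads in the smallest library (R206) and 145937000 in the largest (RP8), and 3 reads corresponded to between 0.0196 and 0.0299 CPM (read counts scaled by library size). The labels do not say how many plants stand behind a line, so p-values measure only the spread between these libraries. Within every group the libraries differed by more than counting noise (lowest chi-square per contig 63.9), which separate preparations of the same RNA can do as well. Each library was counted as 1 sample. Susceptible line 1 of cross A (S205) stood apart from the other libraries, with contigs of the Rubisco small chain taking 6.62% of its values. In susceptible line 3 of cross B (SP9) they took 5.17%, and in the other 10 libraries 3.39% to 4.60%.

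The comparison named in the series title concerns IAA2 (AT3G23030), a member of the Aux/IAA family of repressors that auxin receptors mark for degradation through their degron. The S-assembly contigs of IAA2 were lower in resistant than in susceptible lines, at 5.17 ± 0.55 CPM (SD, n = 5) against 16.0 ± 3.76 CPM (SD, n = 7). The log2 difference was -1.51, and no other arrangement of the phenotypes within the crosses was as extreme (two-sided exact permutation p = 0.00333, the smallest that the 300 arrangements can give). The R-assembly contigs of the same gene stood at 8.47 ± 0.875 CPM (SD, n = 5) in resistant and 8.35 ± 2.12 CPM (SD, n = 7) in susceptible lines, a log2 difference of 0.07 (exact permutation p = 0.803). Summed over its 4 contigs, IAA2 stood at 13.6 ± 1.34 CPM (SD, n = 5) in resistant and 24.3 ± 5.87 CPM (SD, n = 7) in susceptible lines, and the log2 difference of -0.77 passed the test (exact permutation p = 0.01). The sums overlapped, with 13.8 CPM in S242 inside the range of 12.3 to 15.3 CPM of the resistant lines. The ratio of R-assembly to S-assembly contigs separated the phenotypes without overlap, with 1.46 to 1.75 in the 5 resistant and 0.486 to 0.550 in the 7 susceptible lines. The log2 difference of that ratio was 1.67 (exact permutation p = 0.00333). Of these tests only that of the IAA2 level, taken as the sum over its 4 contigs, was planned. The sums by assembly and their ratio were not in the design written in advance. An S-assembly contig of IAA2 also heads the authors' deposited comparison, made in mostly the same libraries. The p-values of IAA2 are therefore no independent support for that comparison. Within cross A the summed difference was -0.63 (exact permutation p = 0.3) and within cross B -0.93 (exact permutation p = 0.0667). With 3 lines against 3 and 2 against 4, the exact test within a cross cannot reach 0.05, since its smallest possible values are 0.1 and 0.0667. The difference between the crosses was -0.30 (exact permutation p = 0.411). How reads that match contigs of both assemblies were counted is not given in the sources used here, so the level of any single IAA2 contig is uncertain.

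**Figure D1:**
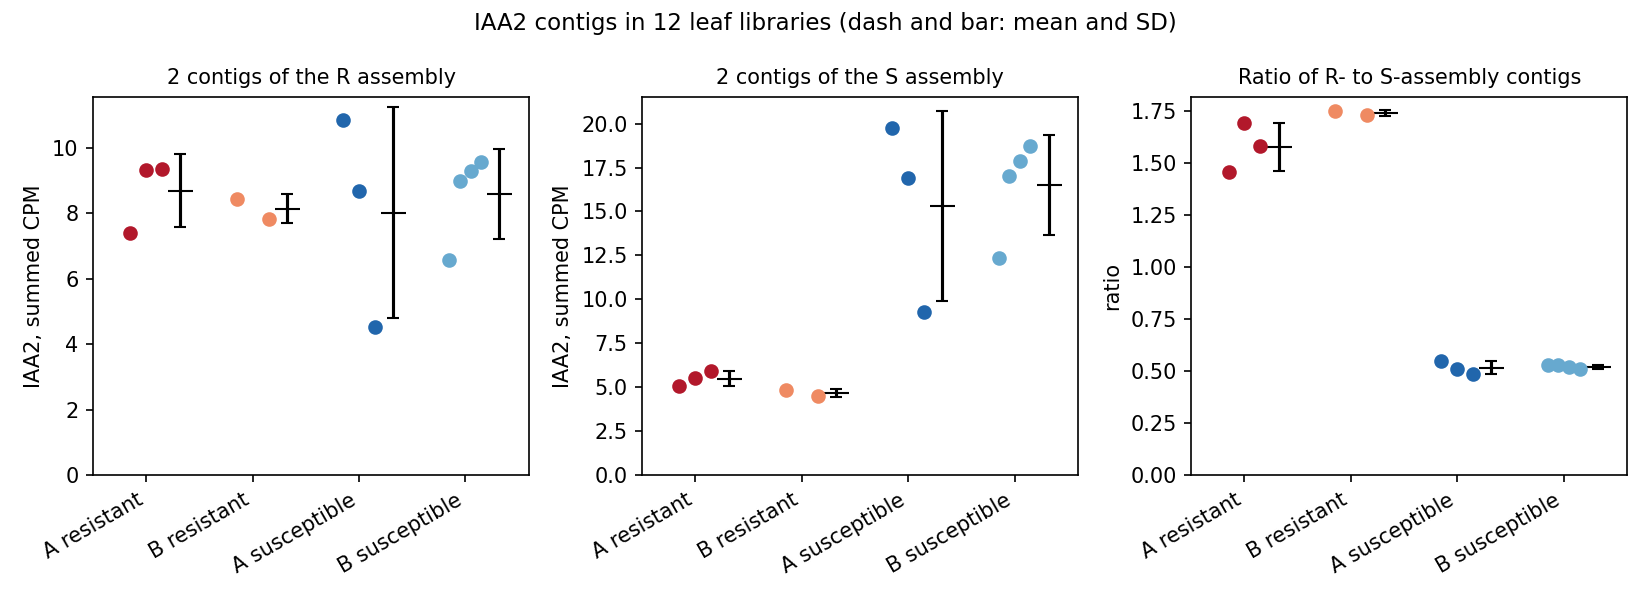
Summed CPM of the 2 R-assembly and the 2 S-assembly contigs of IAA2, and their ratio, in each of 12 leaf libraries by cross and phenotype; points are libraries, dashes and bars the group mean and SD. The S-assembly contigs lie at 4.52 to 5.91 CPM in resistant and 9.31 to 19.7 CPM in susceptible lines, while the ratio lies at 1.46 to 1.75 and 0.486 to 0.550.

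Across both crosses, resistant lines were next compared with susceptible lines over all contigs, with the cross as a covariate. The contig nearest the threshold was an S-assembly contig of IAA2, at 2.61 ± 0.246 CPM (SD, n = 5) in resistant and 9.61 ± 2.37 CPM (SD, n = 7) in susceptible lines (log2 difference -1.66, SE 0.182, limma adjusted p = 0.05002, just above the threshold). It was followed by a contig of AT5G46400, annotated as a tetratricopeptide repeat (TPR)-like protein, at 0.109 ± 0.0613 CPM in resistant and 1.35 ± 0.44 CPM in susceptible lines (log2 difference -1.60, SE 0.194, limma adjusted p = 0.0654). Summed over the S-assembly contigs of that locus, the values were 0.400 ± 0.183 CPM (SD, n = 5) and 3.77 ± 1.19 CPM (SD, n = 7), with a log2 difference of -2.24 (exact permutation p = 0.00333). Its R-assembly contigs stood at 14.6 ± 2.52 and 16.3 ± 2.68 CPM (log2 difference -0.15, exact permutation p = 0.29). These sums were chosen for AT5G46400 after its values were seen. The contigs with the smallest p on the higher side did not pass the adjustment. They included AT3G16150, an Ntn hydrolase, at 5.67 ± 1.3 against 2.04 ± 0.978 CPM (log2 difference 1.29), and AT1G33440, a major facilitator transporter, at 2.91 ± 0.696 against 1.23 ± 0.378 CPM (0.92). The formin AT3G05470 stood at 6.91 ± 0.368 against 4.06 ± 0.967 CPM (0.69), and YUC2, a flavin monooxygenase of auxin synthesis, at 3.65 ± 0.566 against 2.36 ± 0.489 CPM (0.59). On the lower side were also the B3 factor AT4G31620 (log2 difference -0.36), the pfkB-like kinase AT1G19600 (-0.41) and AT3G03150, a protein of unknown function (-0.86). Of 31337 contigs tested, limma called 0 at an adjusted p under 0.05, with 2511 (8.01%) at an unadjusted p under 0.05. On the recovered reads, edgeR called 3, all lower in resistant lines (2395 at unadjusted p under 0.05), and DESeq2 called 84, of which 43 were higher and 41 lower (3218 unadjusted). Leaving out 1 library brought limma to 2 contigs without RP8 or S242 and to 4 without SP9.

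Gene lists of leaf and auxin biology, fixed before the data were examined, were compared between the phenotypes in the same model. Photosynthesis contigs were lower in resistant lines as a group: all 31 had a negative log2 difference, with a median of -0.33 (camera adjusted p = 3.3e-07). The adjusted p was 0.680 with an estimated correlation, and no member passed the test over all contigs or adjusted over the list alone. Among them, a contig of PSBP1, a subunit of the oxygen-evolving complex, stood at 45.1 ± 10.7 CPM (SD, n = 5) in resistant and 77.6 ± 37.0 CPM (SD, n = 7) in susceptible lines. A contig of RBCS1A, a Rubisco small subunit, stood at 6081 ± 332 and 8631 ± 2510 CPM. The high values of S205 and SP9 lie on the susceptible side of this list, and without S205 its adjusted p was 3.888e-05 by camera, within a range of 4.175e-10 to 2.032e-04 over 20 alternatives. The early auxin-response genes were also lower as a group, with 10 of 11 contigs negative and a median of -0.28 (camera adjusted p = 7.4e-04, 0.680 with an estimated correlation, and 0.0535 without S207). Adjusted over the list alone, 2 were lower, the SAUR genes SAUR21 (0.974 ± 0.249 against 1.71 ± 0.43 CPM, log2 difference -0.52) and SAUR64 (0.641 ± 0.192 against 1.3 ± 0.392 CPM, -0.63), whose transcripts rise within minutes of auxin treatment in Arabidopsis. The Aux/IAA repressors were lower with a median of -0.09 over 31 contigs (camera adjusted p = 0.00111, 0.680 with an estimated correlation). Adjusted over the list alone, 2 were lower, and both were the S-assembly contigs of IAA2. The list was not tested without the contigs of IAA2. IAA6 stood at 3.45 ± 0.748 against 5.48 ± 1.26 CPM (-0.56) and IAA1 at 2.74 ± 0.201 against 3.84 ± 0.725 CPM (-0.39), both short of the test.

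Lists of the circadian clock (16 of 18 contigs negative, median -0.17, camera adjusted p = 0.00729), heat shock and protein folding (9 of 10 negative, -0.24, 0.0158) and glutathione S-transferases (43 of 60 negative, -0.10, 0.0158) were lower as groups too. Each had an adjusted p of 0.680 with an estimated correlation and 0 limma calls among its members, also when adjusted over the list alone. BOA, a clock transcription factor, stood at 5.38 ± 1.11 against 7.11 ± 1.21 CPM, and HSP70 at 11.7 ± 4.59 against 15.8 ± 5.86 CPM. Leaving out 1 library ended the call of the clock (0.0761 without R206), of heat shock (0.0717 without R206, 0.0963 without RP6, 0.15 without S242 and 0.065 without SRP1) and of glutathione S-transferases (0.065 without R206, 0.166 without R221, 0.123 without S205, 0.0853 without S242 and 0.0535 without SP9). Higher as groups were the stomatal lineage, the dividing cells and the auxin response factors. Of the 14 stomatal contigs, 11 were positive, with a median of 0.32 (camera adjusted p = 1.8e-04, 0.680 with an estimated correlation). EPF1, a secreted peptide that spaces stomata, stood at 3.46 ± 0.31 against 2.60 ± 0.55 CPM, and FAMA, a transcription factor of guard cell formation, at 9.67 ± 0.755 against 7.15 ± 1.91 CPM. Of the 17 contigs of dividing cells, 14 were positive, with a median of 0.42 (camera adjusted p = 7.8e-04, 0.680 with an estimated correlation). The mitotic kinase CDKB2;1 stood at 27.4 ± 1.81 against 19.2 ± 6.78 CPM and cyclin CYCB1;1 at 24.4 ± 3.01 against 17.1 ± 6.65 CPM. The auxin response factors had 18 of 26 contigs positive and a median of 0.11 (camera adjusted p = 0.0158, 0.680 with an estimated correlation). Adjusted over the list alone, 1 contig of ARF1 was higher (14.1 ± 1.09 against 12 ± 1.08 CPM) and 1 of ARF10 lower (7.55 ± 0.75 against 9.98 ± 1.15 CPM). This list did not pass without R202 (0.0584), R221 (0.0881), RP8 (0.142), S207 (0.0516), SP7 (0.0504) or SRP1 (0.0575). No member of the stomatal or dividing-cell list passed either test.

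**Figure D2:**
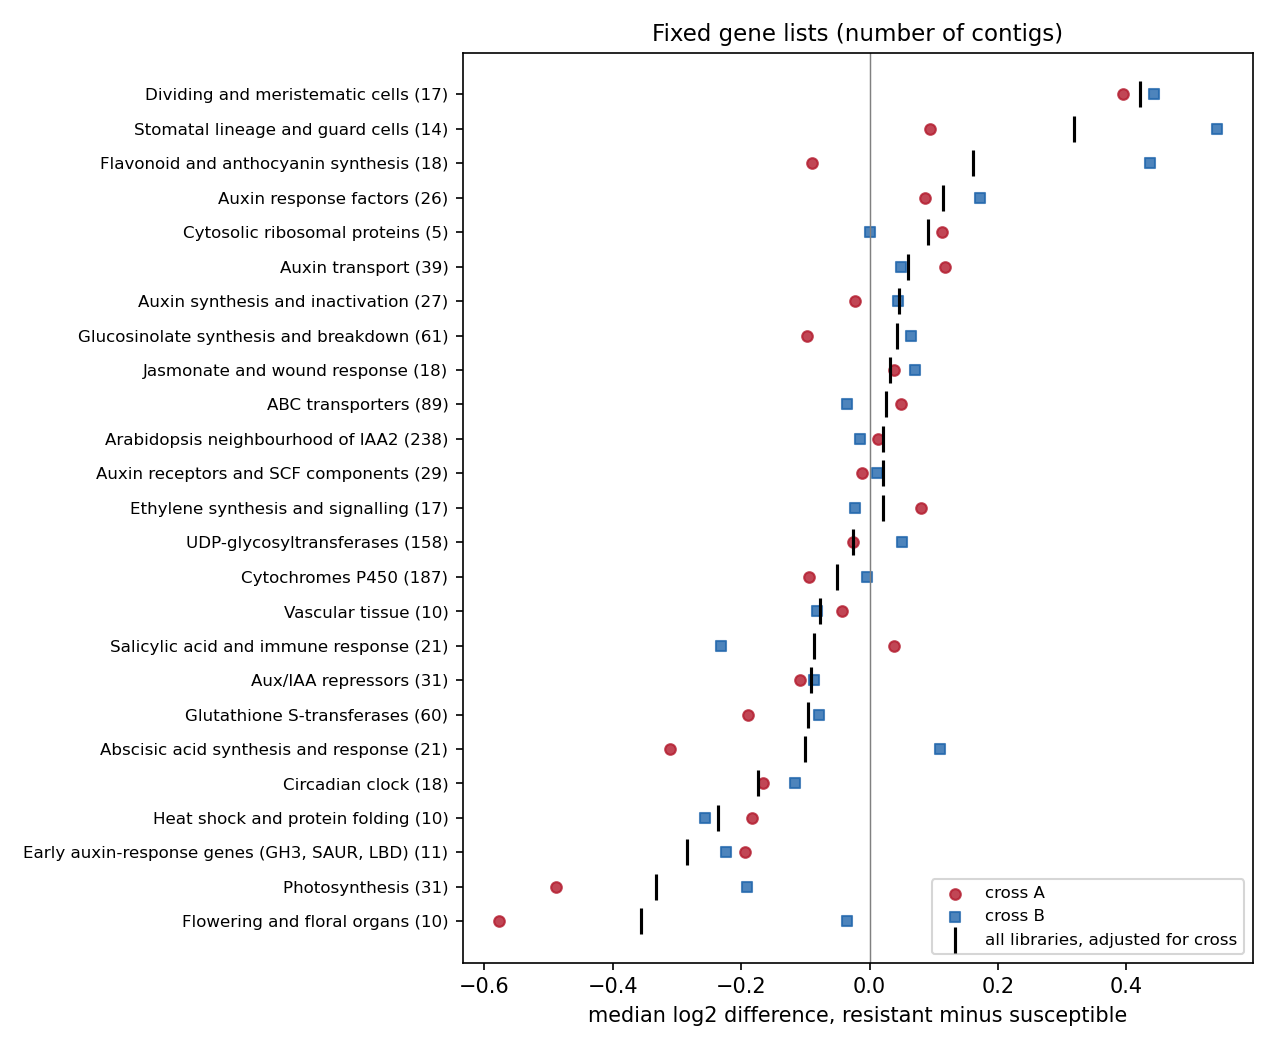
Median log2 difference (resistant minus susceptible) of each fixed gene list within cross A (circles), within cross B (squares) and over all libraries with cross as a covariate (bars), with the number of contigs in brackets. Photosynthesis lies at -0.49 in cross A and -0.19 in cross B, and the stomatal lineage at 0.09 and 0.54.

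The other 16 lists tested across both crosses did not pass. Auxin transport had a median of 0.06 (camera adjusted p = 0.175), auxin synthesis and inactivation 0.05 (0.460), auxin receptors 0.02 (0.954), ethylene 0.02 (0.883), abscisic acid -0.10 (0.377) and salicylic acid and immune response -0.09 (0.152). Jasmonate had 0.03 (0.702), flavonoids 0.16 (0.174), glucosinolates 0.04 (0.954), vascular tissue -0.08 (0.356), flowering -0.36 (0.240) and cytosolic ribosomal proteins 0.09 (0.738). The detoxification families stood at -0.05 (cytochromes P450, 0.356), -0.03 (UDP-glycosyltransferases, 0.702) and 0.03 (ABC transporters, 0.620), and the loci around IAA2 at 0.02 (0.908). For UDP-glycosyltransferases, glucosinolates, ethylene and the loci around IAA2 the mean had the opposite sign to the median (0.06, -0.06, -0.02 and -8.7e-04). For auxin receptors camera pointed lower while median and mean were positive, and for glucosinolates it pointed higher. Adjusted over the list alone, YUC2 was higher, as was 1 contig of the floral gene PISTILLATA (PI) at 2.34 ± 0.651 against 1.37 ± 0.31 CPM. PR2, a glucanase of the salicylic acid response, stood at 19.0 ± 9.53 against 40.4 ± 15.6 CPM, short of the test. With 1 library left out, auxin transport (0.0429 without S205), jasmonate (0.0267 without S205), vascular tissue (0.0469 without S242), flavonoids (0.00556 without R221, 0.0368 without S242) and salicylic acid (0.00951 without R221, 0.0394 without S207, 0.0187 without S242) passed. The senescence list had too few measured members to be tested.

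Genes around the Arabidopsis position of IAA2 were examined as well, although no sequence or genotype was analysed here. Over the 238 contigs of the window, 3 were lower when adjusted over the list alone. Beside the 2 S-assembly contigs of IAA2 this was a contig of AT3G22690, at 12.6 ± 2.66 CPM (SD, n = 5) in resistant and 18.4 ± 2.69 CPM (SD, n = 7) in susceptible lines. The methylation protein gene AT3G22680 stood at 23.4 ± 6.50 against 33.9 ± 4.43 CPM and a contig of the Aux/IAA repressor IAA7 (AT3G23050) at 76.3 ± 6.95 against 97.4 ± 14.6 CPM, both short of the test. With 1 contig per locus, limma called 0 of the 134 loci between AT3G22030 and AT3G24030 and 0 of 15864 outside, so the planned test at the adjusted threshold had nothing to compare (Fisher exact p = 1). In this window edgeR called 1 locus, IAA2 itself, and DESeq2 2 with IAA2 among them, and limma called 1, again IAA2, without S242 or SP9. At an unadjusted p under 0.05, a criterion chosen after seeing the data, 23 loci inside (17.2%) and 1305 outside (8.23%) passed, an odds ratio of 2.31 (95% interval 1.40 to 3.66, Fisher exact p = 7.518e-04). Genes expressed together are not independent, so this p is only a description.

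Within cross A, 1 contig passed the test, an S-assembly contig of the glycosyl hydrolase AT3G06510. It stood at 8.51 ± 1.51 CPM (SD, n = 3) in resistant and 69.2 ± 17.37 CPM (SD, n = 3) in susceptible lines, a log2 difference of -2.93 (SE 0.237, limma adjusted p = 0.0055). In cross B the same contig stood at 9.34 ± 0.505 and 10.9 ± 2.85 CPM, and the difference between the crosses did not pass (2.75, limma adjusted p = 0.132). The R-assembly contigs R_TRINITY_DN1744_c0_g1_i1 and R_TRINITY_DN1744_c0_g2_i1 of this locus had log2 differences of -0.01 and -0.05 over both crosses. Their differences within cross A are not given here, so a change in cross A alone could be hidden. Among the contigs next in rank, all short of the test, were AT3G06450, a bicarbonate transporter family member (12.2 ± 1.17 against 33.1 ± 13.3 CPM), and the neutral invertase AT3G06500 (2.97 ± 1.42 against 13.1 ± 4.85 CPM). On the higher side were the nitrile specifier NSP1 (AT3G16400, 1.15 ± 0.0877 against 0.175 ± 0.303 CPM) and the formin AT1G31810 (19.1 ± 2.23 against 9.88 ± 2.77 CPM). The lists of photosynthesis (median -0.49, camera adjusted p = 1.4e-07), glutathione S-transferases (-0.19, 0.00195), abscisic acid (-0.31, 0.0104), early auxin response (-0.19, 0.0111), Aux/IAA repressors (-0.11, 0.0353) and the clock (-0.17, 0.0426) were lower, and that of dividing cells was higher (0.40, 0.0353). All 7 had an adjusted p of 0.873 with an estimated correlation. With S205 left out the dividing cells pointed lower (0.718), and their call also ended without R206 (0.117), R221 (0.212) or SP9 (0.0555). The Aux/IAA call ended without R202 (0.193), R221 (0.0734), S205 (0.718) or S207 (0.105), and that of early auxin response without S207 (0.549) or SP9 (0.0598). The clock did not pass without R202 (0.257), R206 (0.464), S205 (0.160), S207 or S242 (0.0529 each) or SP9 (0.0598), nor the glutathione S-transferases without R221 (0.0734). An S-assembly contig of the glutathione S-transferase GSTU20 had a log2 difference of -2.45 within cross A. Over both crosses this contig stood at 79.2 ± 66.1 CPM in the 5 resistant and 243 ± 254 CPM in the 7 susceptible lines. By edgeR 1 contig was called and by DESeq2 103, and limma called 22 without R202, 98 without R221, 20 without S205, 15 without S207, 3 without SP9 and 2 without R206 or S242. Of the DESeq2 calls 26 were at loci of Arabidopsis chromosome 3. By limma 21 were on it without R202, 7 without R221, 2 without S205 and 6 without S207. Without SP9 or R206 it was 1 each, and without S242 2. The AT3G06510 contig was called in each of these fits.

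Within cross B, 19 contigs of 10 loci passed the test, and all 10 loci lie on Arabidopsis chromosome 3. Higher in the 2 resistant lines were 7 contigs. They included AT3G47800, a galactose mutarotase-like protein, at 17.0 ± 1.07 CPM (SD, n = 2) against 4.95 ± 0.644 CPM (SD, n = 4), with a log2 difference of 1.69 (SE 0.158, limma adjusted p = 0.00761). The glycosyl hydrolases AT3G47010 (6.98 ± 0.705 against 0.577 ± 0.144 CPM, 2.80, adjusted p = 0.0152) and AT3G47040 (5.05 ± 0.557 against 0.381 ± 0.141 CPM, 2.67, adjusted p = 0.0193) rose with it, as did AT3G16150 (6.78 ± 1.54 against 1.43 ± 0.278 CPM, 1.91, adjusted p = 0.0174). The 3 called contigs of AT3G62850, a zinc finger-related protein, had log2 differences of 2.58 to 3.26. Lower were 12 contigs: 6 of the WD40 protein AT3G50590 (log2 differences -1.897 to -1.363), 3 of AT3G19870, a protein of unknown function (-1.74 to -1.59), and 1 each of 3 further genes. EB1A (AT3G47690), which binds growing microtubule ends, stood at 0.382 ± 0.0683 against 3.14 ± 0.707 CPM (-2.03, adjusted p = 0.0435). The major facilitator AT3G45680 stood at 2.04 ± 0.0987 against 6.26 ± 1.19 CPM (-1.39, adjusted p = 0.0464). AT3G22250, a UDP-glycosyltransferase that lies in the window around IAA2, stood at 0.00654 ± 0.00924 CPM, below the level of 3 reads, against 3.21 ± 1.16 CPM (-2.80, adjusted p = 0.0358). In the resistant lines of cross B the called contigs of AT3G50590 (0.00364 to 0.0520 CPM) and AT3G19870 (0.0142 to 0.0357 CPM) were also near or below 3 reads. Differences of contigs this low depend on the pseudocount. With a pseudocount of 2 limma called 3 contigs within cross B, all on chromosome 3. With CPM summed per locus it called 4 loci, 3 of them on chromosome 3. Chromosome 3 holds 19.7% of the loci measured, and 10 of 10 called loci on it gave a Fisher exact p of 8.882e-08, a test chosen after the calls were seen. The 10 loci hold 19 further contigs that did not pass. Of these, 15 contigs of 5 loci had log2 differences of -0.06 to 0.25 in cross B, and 4 of 4 loci went the way of the called contigs by 0.84 to 1.60. At AT3G62850 and AT3G19870 contigs of both assemblies were called.

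Among the lists, the stomatal lineage was higher in the resistant lines of cross B in all 14 contigs, with a median of 0.54 (camera adjusted p = 5.7e-12, 0.120 with an estimated correlation) and 5 contigs higher when adjusted over the list alone. A contig of FAMA had a log2 difference of 0.71 there and of 0.11 in cross A. Flavonoid synthesis was higher (16 of 18 contigs positive, median 0.44, camera adjusted p = 4.7e-04, 0.632 with an estimated correlation). UDP-glycosyltransferases were higher (median 0.05, 0.00166, 0.664 with an estimated correlation), with 22 contigs higher and 3 lower when adjusted over the list alone. A contig of AT2G40190 of that family had a log2 difference of 1.54 in cross B and 0.18 in cross A. Auxin response factors (0.17, 0.00279) and dividing cells (0.44, 0.00279) were higher as well, both at 0.664 with an estimated correlation. Aux/IAA repressors (-0.09, 0.00166), early auxin-response genes (-0.22, 0.0055), salicylic acid and immune response (-0.23, 0.0151), photosynthesis (-0.19, 0.0219) and the clock (-0.12, 0.0496) were lower. These 5 had an adjusted p of 0.664 with an estimated correlation, or 0.769 for photosynthesis. Without RP8 the calls ended for auxin response factors (0.109), early auxin response (0.0679), photosynthesis (0.560), salicylic acid (0.0724), dividing cells (0.115) and UDP-glycosyltransferases (0.0529). Without SP9 they ended for photosynthesis (0.703), salicylic acid (0.116) and dividing cells (0.0968), and without SRP1 for early auxin response (0.124). The clock did not pass without RP6 (0.136), RP8 (0.0776), S205 (0.0593), S207 (0.059), SP9 (0.223) or SRP1 (0.124). By edgeR 26 contigs were called, 18 of them on chromosome 3, and by DESeq2 179, 52 on chromosome 3. Limma called 2 contigs without RP6, with 0 on chromosome 3 and 0 shared with the 19, and 15 without RP8, with 7 on chromosome 3 and 1 shared. It called 73 without SP9 (24 on chromosome 3), 28 without SRP1 (15), 22 without R221 (15), 20 without R206 (18) and 19 without S205 (18). The 4 called without SP3, 5 without SP7 and 12 without S207 were all on chromosome 3.

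**Figure D3:**
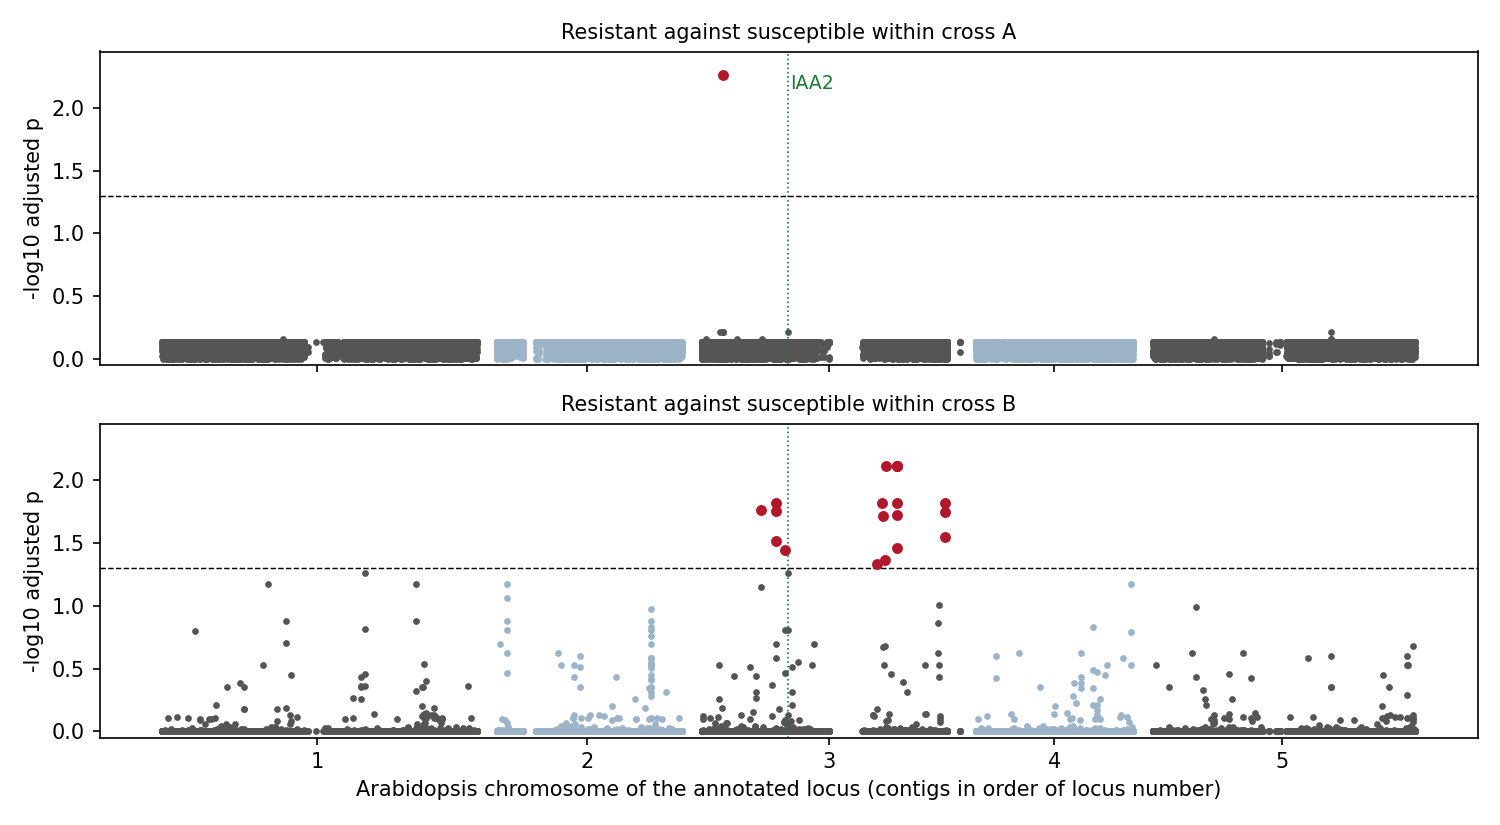
Adjusted p of each contig (as -log10, limma) for resistant against susceptible lines within cross A and within cross B, in the order of the Arabidopsis loci on chromosomes 1 to 5; red points pass the dashed line of 0.05 and the dotted line marks IAA2. The 1 contig called in cross A and the 19 called in cross B lie on chromosome 3.

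The difference between the crosses in the effect of the phenotype was tested itself. The contigs nearest the threshold were those of AT3G47800 (1.91), AT3G47010 (3.31) and AT3G06510 (2.75), each with a limma adjusted p of 0.132. Limma called 0 contigs (1066 at an unadjusted p under 0.05), edgeR 19 (1067 unadjusted) and DESeq2 108 (1456 unadjusted). Of the lists, stomatal lineage (median 0.49, camera adjusted p = 5.2e-07, 0.460 with an estimated correlation) was higher in cross B relative to cross A, as were UDP-glycosyltransferases (0.13, 4.3e-05), abscisic acid (0.53, 3.5e-04), flavonoids (0.57, 0.00111) and glutathione S-transferases (0.14, 0.0107), each at 0.791 with an estimated correlation. Photosynthesis (0.25, 0.0136) and glucosinolates (0.11, 0.0156) were higher too, and ethylene was lower (-0.10, 0.0387). With an estimated correlation the adjusted p of these 3 was 0.828, 0.828 and 0.791. The lists of the stomatal lineage, UDP-glycosyltransferases, abscisic acid and flavonoids passed with any 1 library left out. Photosynthesis did not pass without R202, RP6, S205, S207, SP7 or SRP1 (0.0534 to 0.858), nor glucosinolates without R202, R221, RP6, S205, S242 or SP7 (0.0799 to 0.492). Glutathione S-transferases did not pass without R221, RP6, S205, SP7 or SRP1 (0.057 to 0.185), nor ethylene without R221, RP6, S207, S242, SP3, SP9 or SRP1 (0.0626 to 0.334). Limma called 7 contigs without R202 or RP8, 9 without S205 or S207, 27 without SP9 and 77 without R221.

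The crosses themselves differed far more than the phenotypes. Lower in cross B was a contig of PAC (AT2G48120), the pale cress protein needed for chloroplast development, at 78.8 ± 14.8 CPM (SD, n = 6) in cross A and 0.0752 ± 0.0178 CPM (SD, n = 6) in cross B (log2 difference -7.08, SE 0.122, limma adjusted p = 8.7e-11). A contig of the TIR-NBS-LRR disease resistance gene AT4G19510 fell from 13.9 ± 2.17 to 0.0605 ± 0.0235 CPM (-4.65, adjusted p = 4.2e-10) and a contig of its neighbour AT4G19500 from 9.98 ± 2.12 to a level below 3 reads (-4.32, adjusted p = 5.3e-09). Contigs of the berberine bridge family gene AT5G44410 (7.63 ± 1.02 against 0.00581 ± 0.00911 CPM), of SAG101, an immune signalling protein (3.37 ± 0.773 against 0.00283 ± 0.00692 CPM), and of the nudix hydrolase AT3G10620 (45.1 ± 29.4 against 0.924 ± 0.0889 CPM) were lower in cross B too. Higher in cross B were AT2G25870, a haloacid dehalogenase-like hydrolase, at 1.2 ± 0.413 against 56.9 ± 15.5 CPM (log2 difference 5.05, adjusted p = 1.2e-07), and the CRM domain gene AT3G18390 at 0.462 ± 0.618 against 10.7 ± 3.53 CPM (3.6, adjusted p = 2.3e-04). The R-assembly contig of GSTU20 stood at 203 ± 267 against 1039 ± 371 CPM (3.87, adjusted p = 0.036), the RNA-binding gene AT1G66260 at 0.750 ± 1.17 against 8.94 ± 1.93 CPM (3.42) and germin 3 at 0.729 ± 1.28 against 5.87 ± 1.16 CPM (2.92). As within cross B, a contig could move while another of its locus did not. S_TRINITY_DN20024_c0_g1_i1 of PAC had a log2 difference of 0.35 (limma adjusted p = 0.551) and S_TRINITY_DN14476_c0_g1_i1 of AT5G44410 0.19 (limma adjusted p = 0.393). Limma called 682 of 31337 contigs, 259 higher and 423 lower in cross B, edgeR 532 and DESeq2 1742. The limma count was 246 without S207, 251 without RP8, 272 without SP7, 335 without SP3, 358 without R221, 369 without SRP1, 376 without SP9, 426 without R202, 432 without RP6, 437 without S242 and 1072 without R206.

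Several gene groups differed between the crosses with the phenotype as a covariate. Heat shock genes were lower in cross B (9 of 10 contigs, median -0.61, camera adjusted p = 9.7e-05, 0.769 with an estimated correlation), with 2 called over all contigs and 6 adjusted over the list alone. The chaperone HSP101 fell from 24.1 ± 5.26 to 12.9 ± 4.08 CPM (log2 difference -0.94, adjusted p = 0.0312) and HSP17.6II from 8.07 ± 5.93 to 2.23 ± 0.984 CPM (-1.59, adjusted p = 0.0445). The glucosinolate list, with 33 contigs negative and 28 positive, was lower by camera (median -0.16, adjusted p = 0.0108, 0.769 with an estimated correlation), with 12 contigs lower over all contigs, and 22 lower and 6 higher adjusted over the list alone. A contig of TGG2, a myrosinase that breaks glucosinolates down, fell from 217 ± 49.5 to 43.5 ± 16.4 CPM (-2.30, adjusted p = 4.2e-04). The stomatal lineage (median -0.28, camera adjusted p = 0.00136, 14 of 14 contigs negative), dividing cells (-0.34, 0.00163, 2 lower adjusted over the list alone) and UDP-glycosyltransferases (-0.10, 0.0477) were lower, each at 0.769 with an estimated correlation. The mean log2 level of stomatal contigs hardly differed between resistant lines of cross A (3.11 to 3.28) and cross B (3.15 to 3.22). In susceptible lines it was 2.85 to 3.36 and 2.56 to 2.82. UDP-glycosyltransferases likewise stood at 2.55 to 2.64 and 2.54 to 2.65 in resistant lines, and at 2.60 to 2.80 and 2.28 to 2.59 in susceptible lines. For these lists the difference therefore lay in the susceptible lines. Vascular tissue (10 of 10 contigs positive, median 0.23, 0.00163, 4 higher adjusted over the list alone) and photosynthesis (0.06, 0.0498) were higher, both at 0.769 with an estimated correlation. The xylem peptidase XCP2 stood at 128 ± 23 against 174 ± 25.1 CPM. Without S242 the adjusted p was 0.116 for dividing cells, 0.552 for photosynthesis and 0.0515 each for vascular tissue, glucosinolates and UDP-glycosyltransferases. Glucosinolates did not pass without SP7 (0.056) either, nor photosynthesis without R202 (0.293), RP6 (0.332) or SP9 (0.254), nor UDP-glycosyltransferases without R202 (0.0518), S205 (0.423), SP7 (0.128) or SRP1 (0.113). In auxin transport, which did not pass as a list (0.913), 2 contigs were higher and 4 lower over all contigs. The auxin exporter PIN7 fell from 4.02 ± 2.21 to 0.00461 ± 0.00715 CPM at 1 contig (-2.88, adjusted p = 0.0233), and ABCB14 rose from 1.2 ± 1.15 to 5.49 ± 0.717 CPM (2.1, adjusted p = 0.0233). The remaining 17 lists did not pass.

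The authors' deposited table lists 277 contigs for resistant against susceptible lines, 181 lower and 96 higher in resistant lines. Of these, 8 have an FDR under 0.05 per the authors, 6 lower and 2 higher. These are the 2 S-assembly contigs of IAA2, with log2 fold changes of -1.84 and -1.28 in the authors' deposited table, 3 contigs of AT5G46400 (-3.59, -3.56 and -2.68), AT2G19790, a SNARE-like protein (-1.10), and 2 contigs of P-glycoprotein 13 (AT1G27940), an ABC transporter (2.46 and 1.67). Of the 277 contigs in the authors' deposited table, 201 passed the filter used here, all 201 had the same sign in limma and 112 had an unadjusted p under 0.05. The listed contigs are past a p-value and a fold change limit in mostly the same libraries, so a shared sign is no independent support. The authors' values were matched here only with SRP1 left out (largest deviation 0.00152, against 1.46 with all 12 libraries), so they do not rest on the same libraries as the sum that follows. Summed over its contigs in all 12 libraries, AT1G27940 stood at 32.2 ± 5.48 CPM (SD, n = 5) in resistant and 28.7 ± 9.98 CPM (SD, n = 7) in susceptible lines, a log2 difference of 0.27 (exact permutation p = 0.563).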

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

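Among 270 pairs of a measured value and a group of 4, 5 or 7 libraries, 22 had a library far from the others. Chance gives about 1 in 20 for independent values, but these groups and values overlap. As tests of explanations, the ratio and sum of IAA2 and AT5G46400 contigs, the loci on chromosome 3 and photosynthesis without 1 library or against dividing cells were chosen after those results were seen. The comparisons with other splits of the samples were planned, except for the pairs of splits used for chromosome 3. That around IAA2 uses the unadjusted criterion, which was itself chosen after seeing the data.

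In susceptible line 3 of cross B (SP9), the S-assembly contigs of AT5G46400 stood at 1.2 CPM, where the other susceptible lines had 3.77 to 4.63 CPM. The ratio of R-assembly to S-assembly contigs of that locus was 11.4 in SP9, against 3.21 to 4.86 in the other susceptible lines and 4.43 to 4.86 in those of cross B. The contig S_TRINITY_DN12031_c0_g1_i3 of the locus stood at -0.062 on the log2 scale in SP9, against 0.83 to 1.22. The transporter AT1G33440 (S_TRINITY_DN2582_c0_g2_i1) stood at -0.075 in SP9, against 0.69 to 1.07 in the other susceptible lines and 0.69 to 0.85 in those of cross B. The UDP-glycosyltransferase AT3G22250 stood at 0.99 in SP9 (others of its group 2.04 to 2.17) and EB1A at 1.37 (1.98 to 2.02). The mean level of the vascular genes was 5.11 in SP9, against 4.64 to 4.69 in the other susceptible lines of cross B. On the second principal component (18.8% of the variance) SP9 lay at -58.6, against -6.08 to 2.22.

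Susceptible line 4 of cross B (SRP1) had a mean level of ethylene genes of 4.32 (others of its group 4.26 to 4.27). The CRM domain gene AT3G18390 stood at 2.59 in susceptible line 2 of cross B (SP7), against 3.75 to 3.81, and AT5G44410 at -0.96 in line 1 (SP3), where the other lines of the group were at 0 reads. Resistant line 1 of cross A (R202) had a mean level of photosynthesis genes of 8.61, against 9.26 to 9.52 in the other resistant lines. In the same line the formin AT3G05470 stood at 3.01 (others 2.84 to 2.88) and the invertase AT3G06500 at 2.35 (1.39 to 1.58). GSTU20 stood at 4.36 on its R-assembly contig in resistant line 3 of cross A (R221), against 9.03 to 9.78. Resistant line 2 of cross B (RP8) stood apart from the other resistant lines at contigs that differed between the crosses. AT4G26650 stood at 3.46 in RP8 (others -1 to -0.14) and AT5G66850 at 2.63 (-1 to -0.24). AT3G06540 stood at -0.93 (others 5.05 to 5.39) and AT4G28070 at -0.74 (4.95 to 5.44). At these 4 contigs resistant line 1 of cross B (RP6) had the level of cross A. Resistant line 2 of cross A (R206) had 101 M reads (M for 1e6), where the other resistant lines had 134 to 146 M.

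For 8 gene lists the difference between phenotypes itself differed between the crosses by camera. The adjusted p was 5.249e-07 for the stomatal lineage, 4.335e-05 for UDP-glycosyltransferases, 3.531e-04 for abscisic acid, 0.00111 for flavonoids, 0.0107 for glutathione S-transferases, 0.0136 for photosynthesis, 0.0156 for glucosinolates and 0.0387 for ethylene. With an estimated correlation it was 0.460 for the stomatal lineage and 0.791 or above for the others.

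The S-assembly contigs of IAA2 and of AT5G46400 were lower in resistant lines while the R-assembly contigs of both genes stood near each other. A uniform fall of IAA2 would leave the ratio of the contigs alone, but its log2 value differed by 1.67 (exact permutation p = 0.00333, the smallest possible), and at AT5G46400, picked because its S-assembly contigs were lower (-2.24), the R-assembly contigs did not fall by as much (-0.15, with a difference of 3.18 in the log2 ratio). Reads of an unchanged total that were only divided differently would leave the sum alone, but that of IAA2 differed by -0.77 (exact permutation p = 0.01), although the IAA2 sum of S242 lay among those of the resistant lines, while the sum of AT5G46400 (-0.41) includes the contigs it was picked for and leaves this open, and a preference for R-assembly contigs at all loci is argued against by a median ratio difference of 0.0214 over 3959 loci. A candidate explanation for IAA2 alone is that susceptible and resistant lines carry different sequences, matched to different degrees by the contigs of the 2 assemblies, with a lower level in resistant lines; at AT5G46400 the R-assembly contigs stood at 3.21 to 11.4 times the S-assembly contigs in the susceptible lines too. No sequence was analysed here, so this was not tested, and reads of a changed allele that match no contig would also lower the sum, so a lower level of IAA2 and a loss of reads cannot be separated.

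With all libraries, the contigs that limma called within a cross lie at loci of Arabidopsis chromosome 3, the chromosome of IAA2. In cross A this is 1 contig, and fits without 1 library differed. There 21 of 22 called contigs lay on chromosome 3 without R202, but 7 of 98 without R221 and 2 of 20 without S205. With only the contig of highest mean at each locus, 7 of 7 called loci of cross B lie on it (Fisher exact p = 1.162e-05). This argues against repeated contigs of 1 locus as the whole cause. The p-value rests on the same calls that drew attention to chromosome 3 and treats neighbouring loci as independent. Locus sums called 4 loci, 3 on chromosome 3 and AT2G03710 on chromosome 2. As for the count itself, 2 of the 15 splits of the cross B lines called as many contigs (real 19, highest other 125) and 7 of the 10 splits of cross A (real 1, highest other 192), and these splits are too few for a share under 0.05. Over 150 pairs of splits in both crosses, 16 gave as many chromosome 3 loci at unadjusted p under 0.001 (real 19, highest other 29). Chance is therefore not excluded for this number. It rises with the hits on all chromosomes, so it does not test the share that lies on chromosome 3. In cross B that share was 13 of 28 loci in the real split and 19 of 119 in the split with most hits. In cross A it was 6 of 7 in the real split and 4 of 5 in another, and shares were not compared over all splits. Splits that call up to 192 contigs were not examined for a cause. A segment around IAA2 shared by resistant lines may contribute, but the called loci lay a median of 563 measured loci from IAA2 against 789.5 for all of chromosome 3 (one-sided permutation p = 0.157), and the order of loci in this species was not used here.

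By camera the photosynthesis list was lower and the lists of dividing cells and the stomatal lineage were higher in resistant lines, but each had an adjusted p of 0.680 with an estimated correlation and no member passed the test. Among 100 splits of the samples within the crosses, 9 gave a median of photosynthesis as far below 0 (real -0.33, lowest other -0.51) and 17 one as far from 0 in either direction, the real one included, so chance is not excluded, and 34 called as many lists (real 9, highest other 14). The call by camera with the preset correlation did not need S205, since the adjusted p of the list without S205 was 3.888e-05. This leaves out 1 library only. The mean level of the list was lowest in R202 (8.61) and highest in S205 (9.97) and SP9 (10.08). The other libraries lay at 9.07 to 9.62, and the list was not tested with R202, S205 and SP9 left out together. Leaves at different stages could give this pattern, and the mean levels of photosynthesis and dividing-cell genes had a correlation of -0.479 within groups (permutation p = 0.261, Spearman -0.406 with p = 0.307, and -0.428 without S242 and R202), which leaves this open. No other biological explanation was tested.

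Over all contigs, 100 of 100 splits of phenotype called as many as the real one (real 0, highest other 135), which a count of 0 by limma makes certain (2511 at unadjusted p under 0.05, 3 by edgeR, 84 by DESeq2). Why some splits call up to 135 contigs, and which libraries or contigs carry this, was not examined. For the crosses, 1 of 100 splits called as many contigs, the real one itself (682, highest other 151). This makes chance unlikely there, although not every possible split was drawn. For the loci around IAA2 at unadjusted p under 0.05, 3 of 100 splits gave an odds ratio as large (real 2.31, highest other 3.16). That criterion was chosen after seeing the data, so this share does not rule chance out.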

How the results depend on the processing

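The locus sums, the edgeR exact test, the unadjusted criterion around IAA2, and the sums by assembly and ratio of contigs were chosen after seeing the data. The other alternatives were planned. IAA2 was lower in resistant lines under each alternative run: the log2 difference was -0.71 with a pseudocount of 2, -0.79 with 0.1, -0.83 by edgeR and -0.84 by DESeq2, and -0.94 (without S242) to -0.68 (without S205) with 1 library left out. The number of lists that passed was 6 to 10 with 1 library left out. Photosynthesis, Aux/IAA repressors, the stomatal lineage and dividing cells passed in 20 of 20 alternatives each, median-ratio rescaling included. All were run with the preset correlation of 0.01, while with an estimated correlation each list had a camera adjusted p of 0.680 and did not pass. None of these alternatives left the contigs of IAA2 out of the Aux/IAA list. The clock missed without a filter (0.0633) and with 1 CPM in 2 libraries (0.0641), and heat shock without the covariate (0.304).

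For resistant against susceptible lines, limma called 0 contigs, and 2 with a pseudocount of 0.1, 1 without the covariate, 3 by edgeR and 84 by DESeq2. The exact test called 9 with 12 libraries and 8 without SRP1. With 1 library left out the count was 0 to 4 (2 without RP8 or S242, 4 without SP9). Around IAA2, 1 locus, IAA2 itself, was called with a pseudocount of 0.1, by edgeR and without the covariate, 2 by DESeq2, and 0 to 1 with 1 library left out (1 without S242 or SP9).

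Within cross A the count of 1 became 103 by DESeq2 and 0 with locus sums, where contigs of 1 locus are added together. With 1 library left out it was 1 to 98 (R202 22, R206 2, R221 98, S205 20, S207 15, S242 2, SP9 3). Within cross B the count of 19 became 3 with a pseudocount of 2, 179 by DESeq2 and 4 with locus sums. With 1 library left out it was 2 to 73 (RP6 2, S207 12, SP3 4, SP7 5, SP9 73). Without RP6 or RP8 the lone resistant line of cross B is assumed to vary like the other groups. The difference between crosses had 0 calls by limma, 11 with a pseudocount of 0.1, 1 without a filter, 1 with 1 CPM in 2 libraries, 19 by edgeR and 108 by DESeq2. It had 0 to 77 with 1 library left out (R202 7, R221 77, RP8 7, S205 9, S207 9, SP9 27). For the crosses the count of 682 became 1742 by DESeq2, 200 with locus sums, which test fewer units, and 246 to 1072 with 1 library left out. Where not stated, the cause was not tested.

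Some results changed sign with 1 library left out. The R-assembly contigs of IAA2 ranged from -0.11 (without S242) to 0.17. The ribosomal protein contigs R_TRINITY_DN12502_c1_g1_i1 and R_TRINITY_DN3744_c0_g1_i1 ranged from -0.036 and -0.025 (both without S205) to 0.17 and 0.18, and S_TRINITY_DN3100_c0_g1_i1 between crosses from -0.060 (without S242) to 0.13, negative also without R202 (-0.011), S207 (-0.011) and SP9 (-0.035). Within cross A, the adjusted p of the jasmonate list ranged from 0.00565 to 0.794 (lower at 0.0466 without R202, and lower without S207 or S242 too) and that of dividing cells from 1.242e-04 to 0.718 (lower without S205, though the list passed at 0.0353 with all libraries). The cause was not tested. Totals leave out the contig counts, the level of IAA2, the number of lists passing across both crosses and the calls around IAA2. With each alternative taken separately, 6912 results kept their direction and side of the threshold, 139 passed it newly, 402 no longer passed and 9, those above, changed direction. The 7 that moved were numbers of lists called in the other comparisons. Such numbers that stayed similar are counted among the 6912. A further 117, from 40 combinations of a list and a comparison, pointed the other way while missing the threshold both with and without the alternative. Of these combinations 7 concern all libraries: auxin receptors, ethylene, jasmonate, glucosinolates, UDP-glycosyltransferases, ABC transporters and the loci around IAA2. DESeq2 has no counterpart of camera and was not run for lists. Depth limits contigs near 3 reads, 0.0196 to 0.0299 CPM.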

Other observations

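The test of the ratio over all loci, the recomputed table and the assembly of origin were chosen after seeing the data, and they are given as values. Ratios were tested at 3959 loci, those with contigs of both assemblies that summed to a mean of at least 1 CPM in each. The ratio of R-assembly to S-assembly contigs differed between the phenotypes at 2 by limma, IAA2 (log2 difference 1.58, SE 0.0456, adjusted p = 2.628e-08) and AT5G46400 (2.1, SE 0.247, adjusted p = 0.0121), with 286 at an unadjusted p under 0.05. For this test 0.5 CPM was added to each sum. That was not done for the log2 ratio differences of 1.67 and 3.18 given above for these loci. Between the crosses the ratio differed at 82 loci. AT5G46400 lies on chromosome 5 in Arabidopsis, away from IAA2.

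Over all contigs, those of the R assembly had 631 higher and 311 lower in resistant lines at an unadjusted p under 0.05, and those of the S assembly 748 higher and 821 lower. The mean log2 differences were 0.0329 and -0.0275, a gap of 0.0603 (exact permutation p = 0.17). The differences within cross A and within cross B had a correlation of 0.204 over all contigs, with 59.9% of contigs at the same sign.

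The log2 fold changes in the authors' deposited table were matched to within 0.00152 by an edgeR exact test on the recovered reads when susceptible line 4 of cross B (SRP1) was left out. With all 12 libraries the largest deviation was 1.46. The correlation of the stomatal lineage with photosynthesis within groups was -0.208 (permutation p = 0.676, Spearman -0.133 with p = 0.747, and -0.376 without the 2 libraries farthest out).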
